A study of Mus musculus with 15 samples.

How the data were processed

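Polyadenylated RNA of the thoracic aorta was sequenced from 15 adult male C57BL/6 wild-type mice, 5 per group, and each library came from its own animal per the labels. The labels state that libraries were built over 3 days but give no day for any library, so no batch term could be fitted.

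The deposited table held whole-number counts per gene for the 15 libraries, with a gene identifier, a symbol and mm9 coordinates on each of 37681 rows. Per the submitters' processing notes, CASAVA 1.8.2 and STAR 2.5.2a were used and the genome build was mm9. The counting step, its use of strand and the annotation release are not given in the sources used here, so counts of overlapping genes, antisense genes and near-identical copies are uncertain. The counts the authors deposited summed to between 30937046 and 30967115 per library, a spread of 0.0971% of the mean. Raw libraries seldom lie this close, and a step that brought them to a common total is not recorded in the labels. The depth before any such step is therefore unknown, and the edgeR fit treated the deposited counts as counts. All 37 mitochondrial rows held 0 counts, so transcripts encoded by the mitochondrial genome were not measured. Column names matched sample titles, and 0 columns were left without a sample.

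Genes were kept by the filterByExpr function of edgeR 4.0.16 in R 4.3.3, which left 15134 genes holding 99.95% of the counts. Libraries were scaled by the trimmed mean of M-values, with factors from 0.953 to 1.04. One edgeR quasi-likelihood fit with robust dispersions and no covariate covered all 15 libraries, and 3 contrasts were tested: celecoxib against vehicle, rofecoxib against vehicle, and celecoxib against rofecoxib. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. The common biological coefficient of variation was 0.228. Standard errors were derived from the log2 fold change and the F statistic, intervals cover 95%, and CPM values are on the scaled library sizes. List means are means of log2 CPM with a prior count of 2.

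Gene lists were fixed before the data were examined. Of 38 lists, 36 had at least 5 tested members. Each was tested against the remaining genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 36 lists. Each list was also tested with an estimated correlation, with fry (its directional and its mixed test), and by an exact two-sided permutation test of the list mean, chosen after seeing the data, whose smallest possible p at 5 against 5 is 0.00794. Members were in addition adjusted over the list alone. That adjustment covers neither the number of lists nor the comparisons, and members of a list can vary together. Counts of members passing it therefore do not show that single genes changed. The named genes followed a rule fixed before the data were examined. It took up to 10 called genes per direction with a mean of at least 1 CPM, or the 5 genes of smallest p where fewer than 5 were called. It added the 4 members of smallest p in each described list, and Ptgs1, Ptgs2, Ptges, Ptgis, Ptgir, Tbxas1 and Nos3 in every comparison. Described lists were those with a camera adjusted p under 0.001, plus the prostanoid and clock lists, a choice that the fixed rule itself did not state. Predicted genes and pseudogenes were not named, and some genes the rule chose were left out of the text.

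Libraries were compared before averaging: over 12505 genes the smallest chi-square per gene between 2 libraries of a group was 14.7, so no pair agreed within sampling noise. The fit was tested on simulated counts with 200 changed genes in each of 5 runs over 15134 genes. For celecoxib against vehicle it recovered 52.8% of simulated 1.5-fold changes, 74.8% of 2-fold, 90.8% of 4-fold and 96% of 8-fold changes, with 5.19% of calls false. The simulated genes varied independently of each other, so variation shared between genes was left out. These rates may therefore overstate recovery in the deposited libraries.

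Alternatives covered other scalings and filters, DESeq2 1.42.0, limma-voom with and without sample weights, a replicate block, a surrogate variable from sva 3.50.0, tissue covariates, other thresholds and leaving out each library. The 2 comparisons against vehicle share control libraries, so their agreement was set beside 20 simulations of unchanged groups and 20 assignments of the vehicle libraries split 2 and 3. Figures were drawn with matplotlib 3.10.9. Mapped reads, alternative splicing and the mitochondrial transcripts were not analysed here.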

Results

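RNA of the thoracic aorta was sequenced from mice given 1 oral dose of a selective cyclooxygenase-2 inhibitor or of the polyethylene glycol vehicle. Celecoxib, a diaryl pyrazole that carries a sulfonamide, was given at 30 mg/kg, and rofecoxib, a diaryl furanone that carries a methylsulfone, at 10 mg/kg. Each mouse received 100 microlitres by gavage and was killed 6 hours later, at Zeitgeber hour 11, near the end of the light phase. Each of the 3 groups held 5 libraries, each from its own animal. Deposited counts per library lay between 30937046 and 30967115, with 19158 to 19746 genes detected, and the 10 most abundant genes took 8.21% to 9.86% of the counts. The design asks what each compound did to aortic transcripts against vehicle, and whether the compounds differed.

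The largest share of variation did not follow treatment. The first principal component held 47.0% of the variance, and Th and Dbh of noradrenaline synthesis and the neuropeptide Npy were among its 25 leading genes. It was highest in celecoxib 4, rofecoxib 5, vehicle 4 and rofecoxib 3, and its mean did not separate celecoxib from vehicle (exact two-sided permutation p = 0.944). The Schwann cell and nerve list, fixed beforehand, averaged 2.58 ± 1.17 log2 CPM (SD, n = 5) in vehicle, 2.42 ± 1.86 in celecoxib and 2.37 ± 1.81 in rofecoxib. The second component held 10.9% of the variance and set celecoxib 1 apart, with Mt2, Mt1 and Fkbp5 among its leading genes. The third, at 9.75%, had Ucp1 and Elovl3 of brown fat among its leading genes. Its mean was lower in celecoxib than in vehicle (exact permutation p = 0.0238). For rofecoxib against vehicle the same exact permutation test gave p = 0.0635. The second component gave exact permutation p = 0.230 for celecoxib against vehicle. These values were not adjusted over the components and comparisons tested, so the smallest of them does not show a difference.

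**Figure D1:**
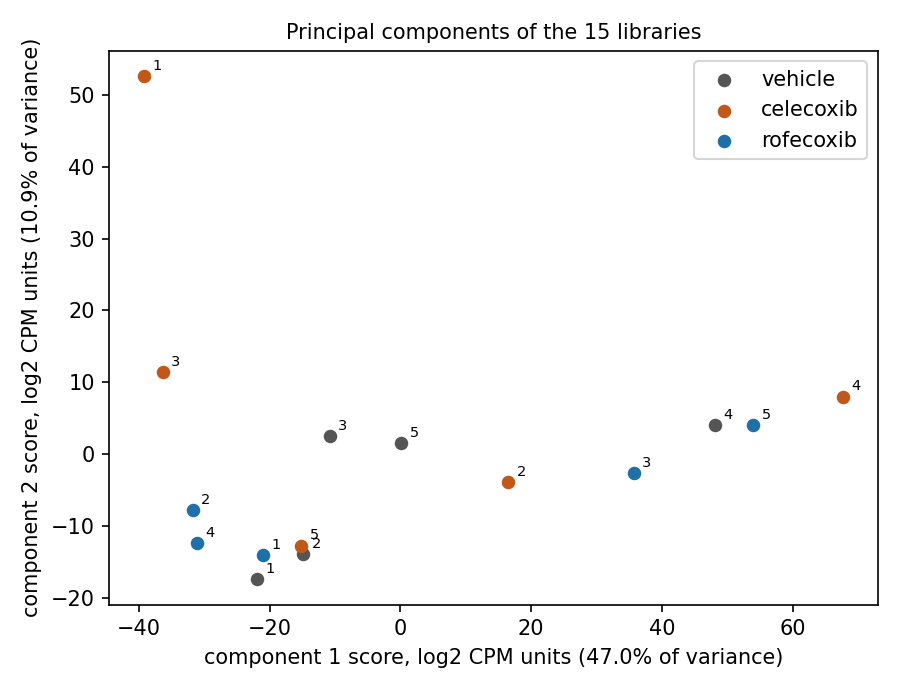
Scores of the 15 libraries on the first component (horizontal axis, 47.0% of variance) and the second (vertical axis, 10.9%), in log2 CPM units, with 1 point per library, replicate numbers beside the points and colours for the groups. Celecoxib 4, rofecoxib 5, vehicle 4 and rofecoxib 3 lie to the right, and celecoxib 1 lies at the top with a second score of 52.6.

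Celecoxib was first set against vehicle. Genes of fat cells and of mitochondrial energy metabolism stood below vehicle as groups, while genes that respond to glucocorticoids stood above it. Camera's calls of these lists were lost, with adjusted p = 0.344 for the fat and mitochondrial lists and adjusted p = 0.387 for the glucocorticoid list with an estimated correlation. Ptgs2, which encodes cyclooxygenase-2 itself, averaged 52.0 ± 22.7 CPM (SD, n = 5) in celecoxib and 25.6 ± 5.35 in vehicle, a 2.03-fold ratio, with 5 of 5 celecoxib libraries above the vehicle median. No single gene passed the threshold over all genes tested.

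The brown adipocyte list, markers of the heat-producing fat that surrounds the thoracic aorta, had a median log2 fold change of -1.12 in celecoxib against vehicle. Of its 22 tested members 20 had a negative sign, and 13 passed when adjusted over the list alone, against 0 over all genes tested. Elovl3, a fatty acid elongase of brown fat, averaged 0.728 ± 0.513 CPM in celecoxib and 6.34 ± 7.58 in vehicle, where vehicle 5 alone reached 19.7. Without vehicle 5 its log2 fold change was -2.04 in place of -3.12, and that of Gmpr -0.75 in place of -1.15. Gyk, the glycerol kinase, stood at 0.535-fold of vehicle, the nucleotide enzyme Gmpr at 0.452-fold and the potassium channel Kcnk3 at 0.456-fold. In the white and general adipocyte list the median log2 fold change was -0.91, and 14 of 23 members passed adjusted over the list alone. Fabp4, the fatty acid carrier of adipocytes, averaged 551 ± 221 CPM against 1028 ± 347 in vehicle. Gpd1 stood at 0.294-fold, the glycerol channel Aqp7 at 0.486-fold and the triglyceride enzyme Dgat1 at 0.625-fold. The fatty acid synthesis list had a median of -0.50, with 2 of 22 members, Gpam at 0.572-fold and Agpat2 at 0.402-fold, passing over the list alone. Srebf1, a regulator of lipid synthesis, stood at 0.776-fold and Elovl5 at 0.878-fold.

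Transcripts for burning fuel lay on the same side. The oxidative phosphorylation and citrate cycle list had a smaller median, -0.38 on the log2 scale, but 36 of its 40 members passed adjusted over the list alone, all of them lower, and 0 over all genes tested. Citrate synthase, Cs, averaged 268 ± 41.5 CPM in celecoxib and 381 ± 69.8 in vehicle. Fh1 stood at 0.703-fold, Suclg1 at 0.669-fold and the respiratory complex subunit Ndufb5 at 0.763-fold, each in 5 of 5 libraries below the vehicle median. The fatty acid oxidation list had a median of -0.62, with 21 of 34 members lower and 1 higher adjusted over the list alone. Ucp3, a mitochondrial carrier induced by fatty acids, averaged 3.03 ± 2.79 CPM against 20.3 ± 10.5 in vehicle. Plin2, which coats lipid droplets, stood at 0.483-fold, Hadha at 0.673-fold and Acaa1b at 0.371-fold. Camera gave adjusted p = 3.75e-32 for oxidative phosphorylation, 2.60e-18 for fatty acid oxidation, 3.53e-17 for brown adipocyte, 9.44e-15 for white adipocyte and 1.34e-10 for fatty acid synthesis. For all 5 lists the call was lost, with adjusted p = 0.344 with an estimated correlation. With the mean of the white and brown adipocyte genes as a covariate, which shares 0 genes with the oxidative phosphorylation list, the median of that list was -0.01 and its call ended.

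Glucocorticoid-responsive genes had a median log2 fold change of 0.60 in celecoxib against vehicle, with 26 of 27 members of positive sign and 4 passing adjusted over the list alone. These were the protease gene Adamts1 at 1.55-fold, Sesn1 at 1.40-fold, Hif3a at 2.42-fold and the clock gene Per1 at 1.62-fold. Camera gave adjusted p = 3.14e-11 for the list, and adjusted p = 0.387 with an estimated correlation. The median was 0.23 without celecoxib 1, the library at the edge of the second component. In the prostanoid list 3 of 35 members passed adjusted over the list alone: Ptgs2, higher, and the prostaglandin E synthase Ptges2 at 0.734-fold and the prostaglandin E receptor Ptger1 at 0.875-fold, both lower. The list as a whole was not called by camera (adjusted p = 0.110). Lta4h of leukotriene synthesis stood at 0.919-fold. The circadian clock list was called higher by camera (adjusted p = 0.0395, and adjusted p = 0.506 with an estimated correlation), yet 0 of 22 members passed adjusted over the list alone and members lay on both sides. Wee1 stood at 1.45-fold and Per3 at 1.28-fold of vehicle, and Npas2, which partners the clock's positive arm, at 0.638-fold. The clock median of 0.09 was 0.05 without celecoxib 1, 0.16 without celecoxib 4 and 0.15 without celecoxib 5. Its call ended without celecoxib 1, 2 or 3 or vehicle 2, 3 or 4. The log2 fold change of Npas2 was -0.37 without vehicle 3 in place of -0.65, and that of Lta4h -0.08 without celecoxib 1 in place of -0.12. The remaining lists called by camera were small shifts. Smooth muscle contractile genes (median log2 fold change 0.09) and cholesterol synthesis genes (0.14) were higher, and chaperones (-0.17), endothelial markers (-0.16), hypoxia and glycolysis genes (-0.07) and carbonic anhydrases (-0.17) lower. Their adjusted p ranged from 0.475 for the carbonic anhydrases to 0.684 for the smooth muscle list with an estimated correlation. These medians also moved with single libraries. The chaperone median was -0.07 without vehicle 5 and -0.09 without celecoxib 1 or celecoxib 2. The endothelial median was -0.07 without celecoxib 3, which ended its call, -0.10 without vehicle 4 and -0.29 without celecoxib 5. The hypoxia median was -0.04 without celecoxib 5 and -0.11 without vehicle 1 or vehicle 2, and its call ended without celecoxib 2 or vehicle 5. The carbonic anhydrase median was -0.11 without vehicle 5, which ended its call, and -0.26 to -0.31 without celecoxib 1, 4 or 5 or vehicle 3. The smooth muscle median was 0.16 without vehicle 2, and its call ended without celecoxib 3, vehicle 3 or vehicle 4. The cholesterol median was 0.08 without vehicle 3, 0.21 without celecoxib 5 and 0.24 without vehicle 2, and its call ended without celecoxib 1, celecoxib 4, vehicle 3 or vehicle 5.

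**Figure D2:**
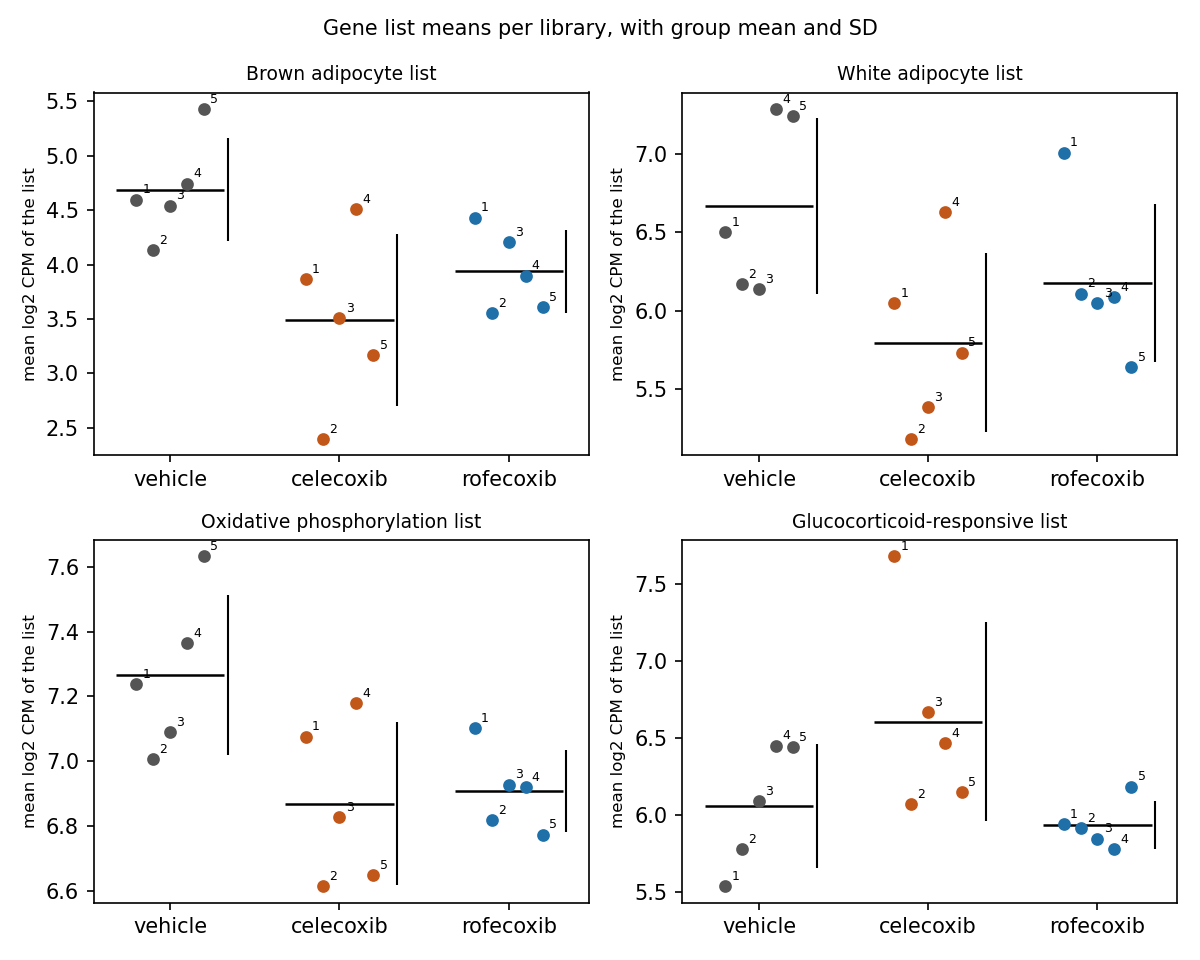
Mean log2 CPM of 4 gene lists in each library, with replicate numbers beside the points, the group mean as a horizontal line and the SD (n = 5) as a vertical bar. The brown adipocyte list averaged 4.69 in vehicle, 3.49 in celecoxib and 3.94 in rofecoxib, and celecoxib 1 was highest in the glucocorticoid-responsive list at 7.68.

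By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15134 genes were called between celecoxib and vehicle, with a smallest adjusted p of 0.146. At an unadjusted p under 0.05 there were 1896 genes, 810 higher and 1086 lower, where 757 would be expected by chance. Chance counts spread widely around that. Fitted on the 10 libraries of the comparison alone there were 1326 genes. Of 100 splits of these libraries, the real one included, 17 gave as many, up to 2498. The 5 genes of smallest p once transcripts without a gene name were left out, none past the threshold, were the retinol dehydrogenase gene Dhrs9 at 0.165-fold, Anxa8 at 0.351-fold, the mitochondrial chaperonin genes Hspe1 at 0.783-fold and Hspd1 at 0.685-fold, and Cdc14a at 1.37-fold. Ptgs2 lies on chromosome 1 from 151947052 to 151955342 of mm9. Its log2 fold change was 1.02 ± 0.26 (SE), with an adjusted p of 0.269 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It was 0.73 without celecoxib 5, which held 90.8 CPM where the other celecoxib libraries held 30.8 to 47.9. Ptgs1 of the constitutive cyclooxygenase averaged 16.0 ± 4.64 CPM against 15.2 ± 3.74, prostacyclin synthase Ptgis 1095 ± 151 against 1049 ± 110, and endothelial nitric oxide synthase Nos3 29.9 ± 9.60 against 38.2 ± 11.6. Ptges stood at 0.688-fold, the prostacyclin receptor Ptgir at 0.880-fold and thromboxane synthase Tbxas1 at 0.730-fold. Without vehicle 4 the log2 fold change was -0.33 for Ptges in place of -0.54 and -0.15 for Nos3 in place of -0.35, and without vehicle 1 it was -0.07 for Tbxas1 in place of -0.45. For Nos3 it was -0.55 without celecoxib 5, and for Tbxas1 -0.26 without celecoxib 3. For Ptgir it was -0.37 without celecoxib 2, in place of -0.18, and -0.05 to -0.11 without celecoxib 1, 3 or 4 or vehicle 1 or 3. The sign turned for Ptgs1 without celecoxib 5 (-0.03) and for Ptgis without celecoxib 3 (-1.25e-05). DESeq2's Wald test called 126 genes, 33 higher and 93 lower, with Ptgs2, Dhrs9 and Ucp3 among them, while limma-voom called 0 with 1866 genes at an unadjusted p under 0.05 and 0 with sample weights. edgeR called 8 genes without celecoxib 4, 1 without celecoxib 5 and 2 without vehicle 2.

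**Figure D3:**
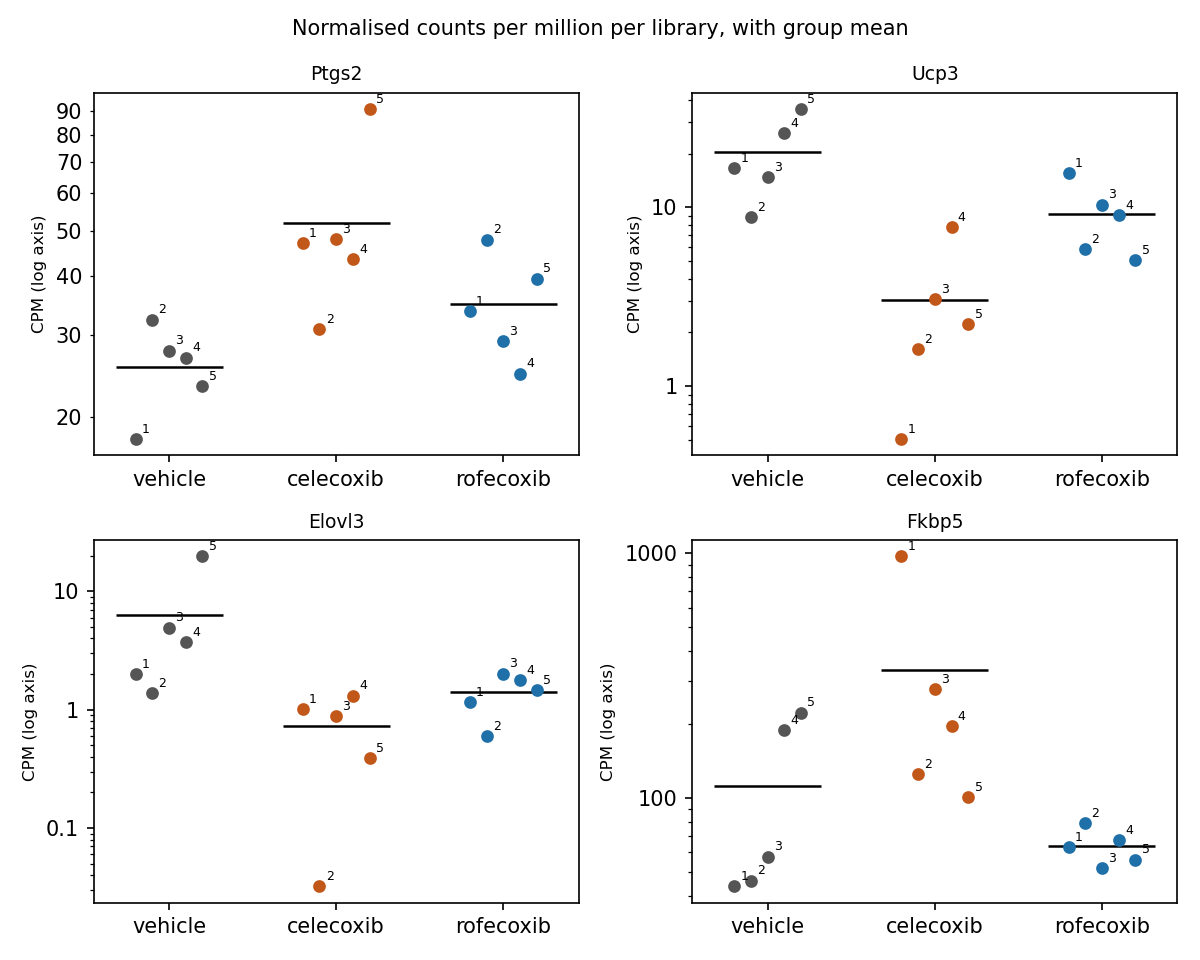
Normalised CPM of 4 genes in each library on logarithmic vertical axes, with replicate numbers beside the points and the group mean as a line. Ptgs2 averaged 25.6 CPM in vehicle, 52.0 in celecoxib and 35.0 in rofecoxib, and Ucp3 20.3, 3.03 and 9.19.

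Rofecoxib against vehicle gave the same groups of fat and mitochondrial genes on the low side, with smaller medians for the adipocyte lists. The smooth muscle contractile list stood slightly above vehicle. Camera's calls of these lists were lost, with adjusted p = 0.273 to 0.519 for the fat and mitochondrial lists and adjusted p = 0.420 for smooth muscle with an estimated correlation. Ptgs2 averaged 35.0 ± 9.03 CPM against 25.6 ± 5.35 in vehicle, a 1.36-fold ratio, with 4 of 5 rofecoxib libraries above the vehicle median. Here too no single gene passed over all genes tested.

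All 40 members of the oxidative phosphorylation list had a negative sign under rofecoxib, with a median log2 fold change of -0.36. Of these, 37 passed adjusted over the list alone, against 0 over all genes tested. The cytochrome oxidase subunit genes Cox7a2 and Cox5b stood at 0.794-fold and 0.737-fold, Uqcrb at 0.820-fold and Cs at 0.750-fold. All 34 fatty acid oxidation genes also had a negative sign, with a median of -0.46, but 0 passed adjusted over the list alone. Plin2 stood at 0.608-fold, and the acyl-CoA enzymes Hadha at 0.726-fold, Acads at 0.716-fold and Acadvl at 0.656-fold. The brown adipocyte list had a median of -0.86, and 3 of 22 members passed adjusted over the list alone: the thyroid hormone deiodinase Dio2, 49.7 ± 8.54 CPM against 93.6 ± 38.0, Gyk at 0.642-fold and Gmpr at 0.547-fold. Elovl3 stood at 0.222-fold, with vehicle 5 far above the other vehicle libraries. Without vehicle 5 the brown median was -0.54, and the log2 fold change was -1.10 for Elovl3 in place of -2.17 and -0.48 for Gmpr in place of -0.87. The white adipocyte list had a median of -0.51 and the fatty acid synthesis list of -0.56, each with 0 members passing over the list alone. The fatty acid synthesis median was -0.35 without vehicle 5 and -0.36 without vehicle 4. The white adipocyte median was -0.34 without vehicle 4 and -0.77 without rofecoxib 1. Gpd1 stood at 0.399-fold, Fabp4 at 0.666-fold, Dgat1 at 0.717-fold, Pnpla2 at 0.682-fold, Fasn at 0.507-fold, Acaca at 0.667-fold, Mlxipl at 0.632-fold and Gpam at 0.694-fold. Without vehicle 5 the log2 fold change was -0.85 for Gpd1 in place of -1.32 and -0.33 for Gpam in place of -0.53. Camera gave adjusted p = 6.20e-47 for oxidative phosphorylation and 1.75e-15 for brown adipocyte. With fatty acid oxidation, these lists had adjusted p = 0.273 with an estimated correlation, fatty acid synthesis had 0.420 and white adipocyte 0.519. With the mean of the adipocyte genes as a covariate the oxidative phosphorylation median was -0.13.

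Smooth muscle contractile genes had a median log2 fold change of 0.11 under rofecoxib, with 24 of 26 members of positive sign and 0 passing adjusted over the list alone. Myh11, the smooth muscle myosin, averaged 12083 ± 932 CPM against 11016 ± 924, Myocd stood at 1.31-fold, Cav1 at 1.11-fold and Csrp1 at 1.12-fold. Hypoxia and glycolysis genes (median -0.14) were lower, with Ldha at 0.779-fold, Eno1 at 0.774-fold, Hk2 at 0.706-fold and Vegfa at 0.750-fold, and so were endothelial markers (-0.17), with Flt1 at 0.830-fold, Egfl7 at 0.769-fold, Sox18 at 0.758-fold and Cldn5 at 0.795-fold. Neither list had a member passing over the list alone. Camera called these 3 lists, with adjusted p = 0.420, 0.420 and 0.540 in that order with an estimated correlation. The endothelial median was -0.05 without rofecoxib 2, which ended its call, -0.07 without vehicle 4 and -0.27 without rofecoxib 1. Without rofecoxib 2 the log2 fold change was -0.23 for Egfl7 in place of -0.38, -0.23 for Sox18 in place of -0.40 and -0.20 for Cldn5 in place of -0.33, and for Sox18 it was -0.26 without vehicle 4. The hypoxia median was -0.07 without vehicle 5 and -0.09 without vehicle 4 or rofecoxib 3, and Hk2 had -0.25 in place of -0.50 without vehicle 5. The smooth muscle median was 0.17 without vehicle 2. In the prostanoid list Ptger1 passed adjusted over the list alone, at 0.850-fold. Ptges2 stood at 0.786-fold, Ephx2 at 0.671-fold and Ltc4s at 0.650-fold, and the list as a whole had adjusted p = 0.0479 by camera and adjusted p = 0.540 with an estimated correlation. The prostanoid median of -0.08 was -0.15 without rofecoxib 1, -0.00453 without rofecoxib 2 and -0.01 without vehicle 4, and the call ended without rofecoxib 2, 4 or 5 or vehicle 1 or 4. The log2 fold change of Ltc4s was -0.27 without vehicle 4 in place of -0.62, and that of Ephx2 -0.87 without rofecoxib 1 in place of -0.58. Of the clock genes, not called as a list, Arntl stood at 0.377-fold, Per3 at 1.28-fold and Wee1 at 1.38-fold. The log2 fold change of Arntl was -0.80 without vehicle 3 in place of -1.41. The other 9 lists that camera called, all lower, held chaperones, blood cell genes, inflammatory genes, cholesterol synthesis, antioxidant response, xenobiotic metabolism, carbonic anhydrases, immediate early genes and lymphocyte markers. None had a member passing over the list alone, and their adjusted p lay between 0.519 and 0.624 with an estimated correlation. All 9 calls also ended without 1 library or another. The chaperone call ended without rofecoxib 4, the blood cell call without vehicle 3, the inflammatory call without vehicle 1 or 3, the antioxidant call without rofecoxib 3 or vehicle 5, and the cholesterol call without rofecoxib 4 or vehicle 1 or 2. The xenobiotic call ended without rofecoxib 4 or 5 or vehicle 4 or 5, and the carbonic anhydrase call without rofecoxib 2, 3, 4 or 5 or vehicle 4 or 5. The immediate early call ended without rofecoxib 3 or 4 or vehicle 2, 3, 4 or 5, and the lymphocyte call without celecoxib 2, 3, 4 or 5, rofecoxib 2, 3, 4 or 5 or vehicle 1, 3 or 4.

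By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15134 genes were called between rofecoxib and vehicle, with a smallest adjusted p of 0.896. At an unadjusted p under 0.05 there were 784 genes, 222 higher and 562 lower, where 757 would be expected by chance. DESeq2's Wald test called 0 and limma-voom 0, with and without sample weights. The genes of smallest p, none past the threshold, were the histone gene Hist1h4h at 0.509-fold, Ptger1, Iffo2 at 0.816-fold, Tspan9 at 0.830-fold and Setd1b at 0.838-fold. Hist1h4h belongs to a family of near-identical copies, so its count is uncertain. Ptgs1 stood at 0.961-fold, Ptges at 0.772-fold, Ptgis at 1.01-fold, Ptgir at 0.873-fold, Tbxas1 at 0.640-fold and Nos3 at 0.799-fold of vehicle. Without vehicle 4 the log2 fold change was -0.17 for Ptges in place of -0.37 and -0.13 for Nos3 in place of -0.32, and without vehicle 1 it was -0.26 for Tbxas1 in place of -0.64. For Ptgir it was -0.07 without rofecoxib 2, -0.12 without vehicle 1 and -0.06 without vehicle 3, in place of -0.20. The sign turned for Ptgs1 without rofecoxib 2 (0.09) or vehicle 4 (0.11), and for Ptgis without rofecoxib 2 (-0.07), vehicle 1 (-0.01) or vehicle 3 (-0.02).

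The compounds were then compared with each other, at doses that differed: 30 mg/kg of celecoxib and 10 mg/kg of rofecoxib. Glucocorticoid-responsive genes stood higher in celecoxib, with a median log2 fold change of 0.71 and 26 of 27 members of positive sign. Camera's call of the list was lost, with adjusted p = 0.587 with an estimated correlation. The 7 members that passed adjusted over the list alone included Hif3a at 2.73-fold, the steroid receptor chaperone Fkbp5 at 5.27-fold, Fam107a at 3.14-fold and the metallothionein Mt2 at 10.3-fold. Fkbp5 averaged 335 ± 363 CPM in celecoxib and 63.5 ± 10.6 in rofecoxib, with celecoxib 1 at 972 and the other celecoxib libraries at 101 to 280. Without celecoxib 1 the log2 fold change of Fkbp5 was 1.47 in place of 2.40, that of Mt2 1.17 in place of 3.36, and the median of the list 0.35.

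Cholesterol synthesis genes had a median log2 fold change of 0.22 between the compounds, with 20 of 24 members of positive sign and 0 passing over the list alone. Lss stood at 1.33-fold, Idi1 at 1.79-fold, Hsd17b7 at 1.70-fold and Sqle at 1.51-fold of rofecoxib. Their list had adjusted p = 0.727 with an estimated correlation, and the log2 difference of Hsd17b7 was 0.48 without celecoxib 1 in place of 0.76. Immediate early genes had a median of 0.21, and Jun, 133 ± 27.5 CPM against 89.1 ± 7.25, was the 1 of 34 members passing over the list alone. Junb stood at 2.02-fold, Btg2 at 1.37-fold and Klf10 at 1.75-fold. Without celecoxib 1 the log2 difference was 0.53 for Junb in place of 1.02 and 0.38 for Klf10 in place of 0.81. The white and brown adipocyte lists were lower in celecoxib, with medians of -0.42 and -0.25 and adjusted p = 0.946 with an estimated correlation. The medians were -0.13 and -0.08 without rofecoxib 1, -0.23 and -0.10 without celecoxib 2 and -0.67 and -0.52 without celecoxib 4, and the brown median was -0.14 without celecoxib 3. Both calls ended without rofecoxib 1 or celecoxib 2, and the brown call also without celecoxib 5 or rofecoxib 3. No member of either passed over the list alone. Plin1 stood at 0.600-fold, Aqp7 at 0.683-fold and Tusc5 at 0.647-fold, while Plin4 stood at 1.44-fold. Without rofecoxib 1 the log2 differences were -0.34 for Plin1, -0.31 for Aqp7 and -0.26 for Tusc5, in place of -0.74, -0.55 and -0.63, and without celecoxib 4 they were -1.15, -0.93 and -1.01. Without celecoxib 1 they were 0.22 for Plin4, in place of 0.53, and -0.42 for Tusc5. Camera also called ribosomal protein genes (median 0.05), cell cycle genes (0.18) and xenobiotic metabolism genes (0.12) higher. These lists had adjusted p = 0.946, 0.946 and 0.727 in that order with an estimated correlation. The ribosomal median was 0.02 without celecoxib 3, which ended its call. The cell cycle median was 0.11 without celecoxib 1 or celecoxib 2, and its call ended without celecoxib 2 or rofecoxib 5 and with the adipocyte covariate. The xenobiotic median was 0.01 without rofecoxib 2, 0.03 without celecoxib 4, 0.20 without celecoxib 3 or rofecoxib 5 and 0.19 without rofecoxib 1, and its call ended without rofecoxib 2, rofecoxib 4 or celecoxib 4. For the glucocorticoid list camera gave adjusted p = 4.72e-15, and adjusted p = 0.587 with an estimated correlation. The immediate early genes had adjusted p = 0.587 as well with an estimated correlation.

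By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 15134 genes differed between the compounds, with a smallest adjusted p of 0.526. At an unadjusted p under 0.05 there were 1053 genes, 613 higher and 440 lower in celecoxib. DESeq2's Wald test called 19 genes, 16 higher and 3 lower, limma-voom called 0 with and without sample weights, and edgeR called 1 without celecoxib 5. The genes of smallest p were Lmcd1, 235 ± 62.7 CPM in celecoxib and 389 ± 15.6 in rofecoxib, the angiopoietin Angpt4 at 2.20-fold, Plekhh1 at 1.99-fold, Prr5l at 0.701-fold and Jun. The compounds were not shown to act alike. The 95% interval of the difference lay within 2-fold for 87.4% of genes, against 86.4% for celecoxib against vehicle and 88.0% for rofecoxib against vehicle. The median SE was 0.111 in each comparison and the shares were close, so they do not tell likeness of the compounds from difference. For Ptgs2 the log2 difference was 0.57, with an interval of 0.02 to 1.12, and it was 0.27 without celecoxib 5. The interval was -0.40 to 0.66 for Ptgs1, -0.70 to 0.37 for Ptges, -0.18 to 0.28 for Ptgis, -0.48 to 0.51 for Ptgir, -0.66 to 1.04 for Tbxas1 and -0.53 to 0.47 for Nos3. The sign of the difference turned for Ptgs1 without rofecoxib 2 (-0.00299), for Ptgis without celecoxib 3 (-0.03), for Ptgir without celecoxib 2 or 5 or rofecoxib 2 or 5 (-0.18 to -0.02), and for Nos3 without celecoxib 1, 2 or 3 or rofecoxib 1 or 3 (0.02 to 0.06). In the prostanoid list Lta4h stood at 0.925-fold, Alox5 at 0.760-fold and Ptgds at 2.18-fold. Ptgds was scarce, at 1.42 CPM in celecoxib 1 and 0.193 to 0.385 CPM in the other celecoxib libraries. Its log2 difference of 1.12 was 0.24 without celecoxib 1. Among clock genes Csnk1e stood at 1.10-fold, Csnk1d at 1.09-fold, Usp2 at 1.45-fold and Npas2 at 0.648-fold. The log2 difference of Csnk1d was 0.08 without celecoxib 1, in place of 0.12. Neither list was called.

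Both compounds were compared with the same vehicle libraries, so their fold changes share chance values. With 0 genes called in either comparison, 0 calls were shared. Across genes, which are not independent replicates, the correlation of the log2 fold changes was 0.620, where simulated unchanged groups against shared controls gave 0.503 on average (0.443 to 0.572 over 20 simulations). With the vehicle libraries split 2 and 3, so that no control was shared, the correlation averaged 0.141 over 20 assignments and ranged from -0.0394 to 0.333. The covariance was 0.0459 observed and 0.0469 simulated. At an unadjusted p under 0.05, 353 genes were lower under both compounds and 68 higher, against 69.2 and 84.4 simulated and 40.3 and 11.9 for independent lists. With split controls 79.8 were lower under both on average, with a range of 12 to 162, and 12.7 higher. The simulated genes varied independently of each other, so genes that move together in the shared vehicle libraries were not reproduced. The gaps between observed and simulated values therefore do not show a shared effect of the compounds.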

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

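All tests of explanations here were chosen after the results were seen. In groups of 5 libraries, 405 groups of values (named genes and list means) were examined for a library whose gap to the next exceeded Dixon's 95% critical value for a share of the range. There were 27 such groups. Among named genes they were 25 of 297, where chance at 1 in 20 gives 14.9, and among list means 2 of 108, where it gives 5.40. The rate of 1 in 20 holds for normally distributed values. Gene values were CPM off the log scale, unlike list means, and many named genes were picked by their p. The excess among genes therefore does not show more outlying libraries than chance gives. Celecoxib 1 was highest in its group for Mt2 (0.879 of the range), Fkbp5 (0.795), Per1 (0.778), Ptgds (0.844) and Csnk1e (0.712). Rofecoxib 1 was highest for Dgat1 (0.863), Ephx2 (0.856), Mlxipl (0.797), Pnpla2 (0.797), Agpat2 (0.754) and Plin1 (0.724), and lowest for Lmcd1 (0.740). Celecoxib 4 was highest for Acads (0.831), Gmpr (0.775) and Plin1 (0.731), and celecoxib 5 for Myocd (0.824) and Ptgs2 (0.715). Vehicle 5 was highest for Elovl3 (0.805), Gmpr (0.769) and Hk2 (0.749), and lowest for the Wnt target list (0.801). Vehicle 3 was highest for Junb (0.820) and Mt2 (0.749) and lowest for Sesn1 (0.788). Vehicle 2 was highest for Plekhh1 (0.751), vehicle 4 for the vascular tone list (0.776) and rofecoxib 5 for Csnk1e (0.813).

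Glucocorticoid-responsive genes stood higher in celecoxib than in rofecoxib, and celecoxib 1 held the highest list mean. Without celecoxib 1 the median log2 fold change was 0.349, under 0.714 with all libraries, so that library carried part of the difference. Whether a difference remains without it is open: the exact permutation p of the list mean was then 0.0317, not adjusted over the lists. By the same exact permutation test p was 0.0556 without rofecoxib 1 or 2 and 0.0635 without rofecoxib 3 or 4. It lay between 0.0159 and 0.0317 without any other library of these 2 groups. With all libraries the exact permutation test gave an adjusted p of 0.429 over the 36 lists. Its smallest possible p is 0.00794, and a list at that floor passes adjustment only if several others reach it, so this result decides nothing. Camera gave adjusted p = 0.587 with an estimated correlation, so an effect of celecoxib was not shown. A rise in the animal's own glucocorticoids through handling, and an effect of the compound, cannot be told apart because the design has no measure of the hormone.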

How the results depend on the processing

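The nerve covariate, leaving out the 4 libraries highest in the nerve list and the exact permutation of list means were chosen after seeing the data; the cause of the changes below was not tested. Genes called stayed at 0 in all 3 comparisons under the other scalings, filters, covariates, thresholds, limma-voom fits, 2-group fits and replicate block. For the thresholds the main fit left no other outcome. A fold-change limit only removes calls, and the smallest adjusted p of edgeR's quasi-likelihood test, 0.146, 0.896 and 0.526, all exceeded 0.10. DESeq2's Wald test called 126 for celecoxib against vehicle and 19 between the compounds. Leaving out 1 library gave 0 to 8 genes for celecoxib against vehicle, 0 for rofecoxib against vehicle and 0 to 1 between the compounds. Shared calls were 0 under every alternative run. With the vehicle group kept whole this was fixed, since rofecoxib against vehicle called 0 genes throughout. Camera's 13, 18 and 8 lists became 0, 0 and 0 with an estimated correlation, 0, 0 and 0 by fry's directional test and 0, 0 and 0 by exact permutation. Exact permutation could hardly give a call. A list at its smallest possible p of 0.00794 passes adjustment over 36 lists only if several others reach it too. Fry's mixed test, which ignores direction, called 4, 0 and 0. The adipocyte covariate left 3 and 10 lists against vehicle, and leaving out the nerve-rich libraries gave 15 between the compounds. Of the 39 list calls, the adipocyte covariate ended 15 and turned 9, leaving out the nerve-rich libraries ended 11, cameraPR on limma-voom 6, the nerve covariate 5, the skeletal muscle covariate 3, the surrogate variable 2, and no filter and the replicate block 1 each. Leaving out 1 library gave 10 to 18, 12 to 19 and 5 to 14 lists, with 5 between the compounds without celecoxib 2, 14 without celecoxib 1 and 13 without celecoxib 4. With the replicate block 14, 17 and 9 lists were called. No pairing by number was seen: same-numbered libraries correlated at -0.0367 on average, 6 of 15 pairs exceeded 0.1, and 4 of 15 libraries correlated best with their own number. These correlations ran from -0.721 to 0.775, so a weak pairing could be hidden and is not excluded. The adipocyte covariate is the mean of the white and brown lists, so what it does to these lists, and their part of the 15 and 9 above, is fixed by construction and decides nothing. The fatty acid synthesis and oxidation lists share some of its genes. Under it medians turned to 0.15 (white adipocyte), 0.0548 (fatty acid synthesis) and 0.12 (carbonic anhydrases) in celecoxib against vehicle, and the hypoxia (0.0206) and smooth muscle (0.0143) tests changed direction. In rofecoxib against vehicle they were 0.0881 (white adipocyte) and 0.0535 (carbonic anhydrases), and between the compounds 0.000564 (white) and 0.0646 (brown). The lymphocyte list in rofecoxib against vehicle ranged from -0.80 to -0.22 with 1 library left out, and its test turned without vehicle 1. With 1 library left out 70 list calls ended, 514 stayed and 1 turned. The signs of some named genes turned, none of them called. For rofecoxib against vehicle these were Ptgs1 (0.00429 with quality weights, 0.13 with the adipocyte covariate, -0.20 to 0.11 with 1 library left out), Ptges (0.00844 without the nerve-rich libraries, from -0.37) and Ptgis (-0.0163 with quality weights, -0.000256 with the nerve covariate, -0.0695 to 0.0622 with 1 library left out). For celecoxib against vehicle, leaving out 1 library gave -0.0321 to 0.24 for Ptgs1 and -1.25e-05 to 0.12 for Ptgis. Between the compounds Ptgir was -0.00905 by library size alone, -0.0116 by limma-voom, -0.18 with the adipocyte covariate and -0.18 to 0.11 with 1 library left out. Tbxas1 was -0.13 without the nerve-rich libraries, and Nos3 was 0.11 with the adipocyte covariate, 0.0937 without the nerve-rich libraries and -0.24 to 0.0575 with 1 library left out. With 1 library left out Ptgs1 was -0.00299 to 0.28 and Ptgis -0.0256 to 0.14. Of 131 named gene values, DESeq2 put 28 past the threshold. The depth before deposit is unknown, so no limit from it was set.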

Other observations

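All tests of explanations in this part were chosen after the results were seen. Some members of other lists passed adjusted over their list alone in celecoxib against vehicle, named here after their values were seen. Camera did not call the p53 and apoptosis list (adjusted p = 0.110) or the antioxidant list (adjusted p = 0.0666). Fry's mixed test, which ignores direction, called the p53 list (adjusted p = 0.0250), the chaperones (0.0290), and the fatty acid oxidation and brown adipocyte lists (0.0315 each). In the p53 and apoptosis list 4 of 29 members passed adjusted over the list alone, in both directions: Trp53inp1 stood at 2.04-fold and Sesn1 at 1.40-fold of vehicle, and the death receptor Fas at 0.740-fold and Phlda3 at 0.711-fold. Sod2, the mitochondrial superoxide dismutase, was the 1 antioxidant gene to pass over its list, at 0.657-fold. Vegfa at 0.586-fold and Egln3 at 0.600-fold passed over the hypoxia list, Car13 at 0.448-fold over the carbonic anhydrases, and Ahsa1 at 0.860-fold, with Hspe1 and Hspd1, over the chaperones. None of these passed over all genes tested.

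Camera called 14 of the lists in no comparison. They held markers of skeletal and cardiac muscle, macrophages, mast cells, fibroblasts, mesothelium and nerve, and genes of vascular tone, haemostasis, extracellular matrix, interferon response, endoplasmic reticulum stress, Wnt targets and p53. Their median log2 fold changes lay between -0.32, for mesothelial genes in rofecoxib against vehicle, and 0.28, also for mesothelial genes, in celecoxib against rofecoxib. Neutrophil markers, with 4 tested members, and thymocyte markers, with 3, were too few to test.

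The counts of calls were set against other splits of the same 10 libraries into 5 and 5, with 100 of 126 splits drawn per comparison, the real one included. For genes past the threshold the real splits called 0, so all 100 of 100 splits call as many whatever the data, and that count decides nothing. The highest other split called 1, 1 and 3 for celecoxib against vehicle, rofecoxib against vehicle and celecoxib against rofecoxib. At an unadjusted p under 0.05, fitted on the 10 libraries alone, celecoxib against vehicle gave 1326 genes, and 17 of the 100 splits gave as many, up to 2498. Rofecoxib against vehicle gave 1043, and 25 splits gave as many, up to 1839. Celecoxib against rofecoxib gave 927, and 26 splits gave as many, up to 2335. For gene lists by camera, celecoxib against vehicle called 14, and 55 of the 100 splits called as many, up to 25. Rofecoxib against vehicle called 17, and 30 splits called as many, up to 24. Celecoxib against rofecoxib called 9, and 86 splits called as many, up to 24. Chance is not excluded for the counts at an unadjusted p or for the lists.

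Adipocyte, fatty acid oxidation and oxidative phosphorylation genes stood below vehicle under both compounds. The mean of the 117 genes of these 4 lists differed between the 10 treated and the 5 vehicle libraries by -0.58 log2 CPM (exact permutation p = 0.0113). It lay below the vehicle median in 9 of 10 treated libraries, but only 2 of the 5 vehicle libraries exceeded the highest treated library. Without vehicle 5 the difference was -0.46, and without vehicle 4 it was -0.53. Both compounds were set against these same vehicle libraries. The permutation test ran on lists picked because they were low, so it decides nothing, and an effect of either compound stays open. With the adipocyte score as covariate the median log2 fold change of the oxidative phosphorylation list was -0.00921 in celecoxib and -0.129 in rofecoxib, from -0.38 and -0.36. The 2 kinds of list share 0 genes, and less fat tissue left on the celecoxib aortas is a candidate explanation of the whole difference. The covariate cannot decide this, since the adipocyte lists were themselves lower in celecoxib. The white list averaged 5.79 log2 CPM against 6.67 in vehicle, and the brown list 3.49 against 4.69. Lower expression of fat and mitochondrial genes in unchanged tissue would give the same result. For rofecoxib it is open whether a remainder exists. A lower thermogenic activity of the fat cells also stays open: the brown minus white list mean differed from vehicle by -0.33 log2 in celecoxib, with an exact permutation p of 0.183, and by -0.21 without celecoxib 2.

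Some transcripts known from sympathetic neurons varied between libraries of every group. A list of 12 sympathetic markers was written after the first component was seen, and 3 of them were among its leading genes. Each marker correlated with the mean of the others over 15 libraries at a median Spearman correlation of 0.907, the lowest being 0.543 for Gata3, which restates the observation and decides nothing about its source. The most abundant reached 182 CPM (Slc6a2), 159 (Dbh) and 87.4 (Th) in celecoxib 4, with medians of 3.40, 1.22 and 0.648 CPM over all libraries. Of the 12 genes, 5 had a median of at least 1 CPM and 2 were in the nerve list fixed beforehand. Sensory neuron markers other than Avil stayed low, with Scn10a at most 0.257 CPM and Trpv1 at most 2.18 CPM, while Avil reached 20.4 CPM in celecoxib 4. The sensory marker mean was still highest in the 4 libraries that were highest on the first component. It was -1.27 log2 CPM in vehicle 4, -1.28 in rofecoxib 5, -1.33 in celecoxib 4 and -1.84 in rofecoxib 3. Sympathetic ganglion tissue left on some aortas is a hypothesis that stays open. The marker mean did not separate treated from vehicle libraries (exact permutation p = 0.839), which does not exclude a difference.

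Clock genes gave a further hypothesis, that the celecoxib group lay at a later clock phase. The mean of 10 genes that peak near dusk minus that of 5 genes that peak near dawn was 0.78 log2 higher in celecoxib than in vehicle (exact permutation p = 0.127) and 0.86 higher in rofecoxib (exact permutation p = 0.0714). Neither passed 0.05 with all libraries, so a shift may exist but was not shown. Without vehicle 3, the lowest at 2.52, the celecoxib difference was 0.52. Without vehicle 1 the exact permutation p was 0.0476 for celecoxib, with a difference of 1.03, and 0.0159 for rofecoxib, with a difference of 1.11. Without vehicle 2 it was 0.0476 for rofecoxib by the same exact permutation test, so the outcome depends on single vehicle libraries. No difference was found between the compounds (-0.08, exact permutation p = 0.802), which does not show that there is none. It was -0.15 without celecoxib 1 or rofecoxib 5, -0.29 without celecoxib 2 and -0.04 without celecoxib 3, and turned to 0.02 without celecoxib 4 or rofecoxib 4 and to 0.08 without celecoxib 5.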
